A study of Camellia sinensis with 12 samples.

How the data were processed

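Leaf RNA from 5-year-old plants of the tea cultivar Yujinxiang was measured by RNA sequencing in 12 libraries, 3 in each of 4 groups. The groups were unshaded leaves of day 5 (D5), leaves after 5 days under a single black net with a shading rate of 65% (SD5), unshaded leaves of day 10 (D10) and leaves of day 10 with 5 days of net followed by 5 days of light (RD10). Group and number of each library were taken from its title in the labels. Per the labels' protocols, RNA was isolated with an Omega plant RNA kit and libraries were made with the TruSeq RNA kit. The labels do not state whether the kit selected polyadenylated RNA, nor whether it kept the strand.

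The values used were whole-number read counts per gene, as deposited, with no normalization in the values themselves. Per the submitters' processing notes, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 1.3.4d and DESeq2 were used by the authors, and the notes give no roles or order for them. How reads that match several genes were counted, and the genome build, are not given in the sources used here, so counts of near-identical gene copies are uncertain. The table gave a description and scaffold position for its 31873 genes, 2812 of which had no description, and gene names are those descriptions. Each entry was paired in the table with a single reference gene ID, no ID was paired with more than a single entry, and those IDs are used. Many entries also carried a transcript assembly ID, so their counts and positions may cover more than the reference gene model. Totals per library ran from 46016956 to 92557886 counts.

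Everything else was computed from these counts with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr on the groups, with a minimum count of 10 and a minimum total of 15, which left 26277. Libraries were scaled by TMM, and edgeR's quasi-likelihood test was fitted to all 12 libraries with group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. There were 5 contrasts: SD5 against D5, RD10 against D10, the difference of these, RD10 against SD5, and D10 against D5. The SE of a log2 fold change is its size divided by the square root of the test's F. Recovery was the slope through the origin, across genes that passed in SD5 against D5, of the RD10 against D10 values on the SD5 against D5 values.

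Gene lists were tested with camera from limma with a preset inter-gene correlation of 0.01, adjusted over the 26 lists of a contrast, and again with an estimated correlation and with fry. The list topics and first name patterns were set before the data were examined. The descriptions in the table used other words than those patterns. Before any test was run, names were therefore added to some patterns and excluded from others. The clock list went from 119 genes by the first names to 24, with 8 in both. The starch and sugar list went from 113 to 74, with 48 in both. Results with the first names alone are given among the alternatives. The caffeine N-methyltransferases are not analysed here. A further list of plastid-genome type genes, and a set of mitochondrial-genome type genes, were added after the data were seen and are counted without a test as a list.

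Genes were named by a rule set in advance. For SD5 against D5 and RD10 against D10 it took the 6 largest rises and 6 largest falls with an adjusted p below 0.05, a mean of at least 5 CPM, groups that did not overlap and an informative name, up to 4 genes of smallest adjusted p from each of the 11 main lists and up to 2 from each other list. For the other contrasts it took 4 rises and 4 falls. A chalcone synthase family member could be named whether it passed or not. Where all libraries of a group had 0 counts, a fold is a lower bound from a floor of 3 counts over the group.

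The fit was tested on simulated counts drawn from the means and library sizes of the real data, with 200 genes changed in shade. In the real SD5 against D5 17212 genes passed, so the Benjamini-Hochberg cutoff was stricter in the simulation. Its recovery shares therefore do not carry over to the real contrasts. For SD5 against D5, 36.4% of genes changed 1.5-fold, 68.3% of those changed 2-fold and 80.3% of those changed 4-fold were recovered, and 6 of 25515 unchanged genes were called, among 25730 genes tested. The simulated RD10 against D10 log2 changes were these times 0.5. For genes changed 1.5-fold, 2-fold and 4-fold in shade, recovery was then 1.52%, 17.5% and 60.6% in RD10 against D10, 0%, 3.17% and 33.3% in the difference, and 3.03%, 15.9% and 62.1% in RD10 against SD5. The simulated slope of 0.5 was fitted as 0.46. Alternatives tried were DESeq2 size factors, DESeq2's Wald test, no low-count filter, the replicate number as a block, a 2-fold minimum, fits to the compared groups alone and leaving out each library, and, chosen after seeing the data, library totals as the only scaling, leaving out organelle-genome type genes, list members by first names alone and D10 as the unshaded group.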

Results

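Leaf RNA was sequenced from the tea cultivar Yujinxiang, an albino form of Camellia sinensis whose young leaves are pale, in 12 libraries that fall into 4 groups of 3. D5 leaves stood in the open and SD5 leaves had spent 5 days under a single black net that took away 65% of the light, and both were picked on day 5. RD10 leaves had the same 5 days of net and then 5 days without it, and D10 leaves stood in the open, and both were picked on day 10. The values were read counts for 31873 genes, and the totals per library ran from 61708043 to 88962921 counts in D5, 54085004 to 92557886 in SD5, 46016956 to 59636891 in D10 and 49436027 to 70418776 in RD10. The labels do not say that libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be technical in part. Levels are CPM, counts scaled to a common library size with TMM factors, as mean ± SD of 3 libraries, and fold changes are log2 values ± SE. Gene positions are on numbered scaffolds, as deposited. The genome build is not given in the sources used here.

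Replicates lay close together and the groups lay far apart. Pearson's r of log CPM across genes was 0.974 to 0.982 for the 12 pairs of libraries within a group and 0.856 to 0.953 for the 54 pairs between groups. The first principal component took 46% of the variance and separated D5 from the other 3 groups, and the second took 24.7% and separated SD5. Of 26277 tested genes, 4983 were higher in D5 than in each of the other groups and 5703 were lower. Transcripts of plastid and mitochondrial genome type took 0.878 ± 0.147% of the counts in D10, against 0.0558 ± 0.00221% in D5, 0.0185 ± 0.00206% in SD5 and 0.0769 ± 0.028% in RD10 (SD, n = 3 each).

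**Figure D1:**
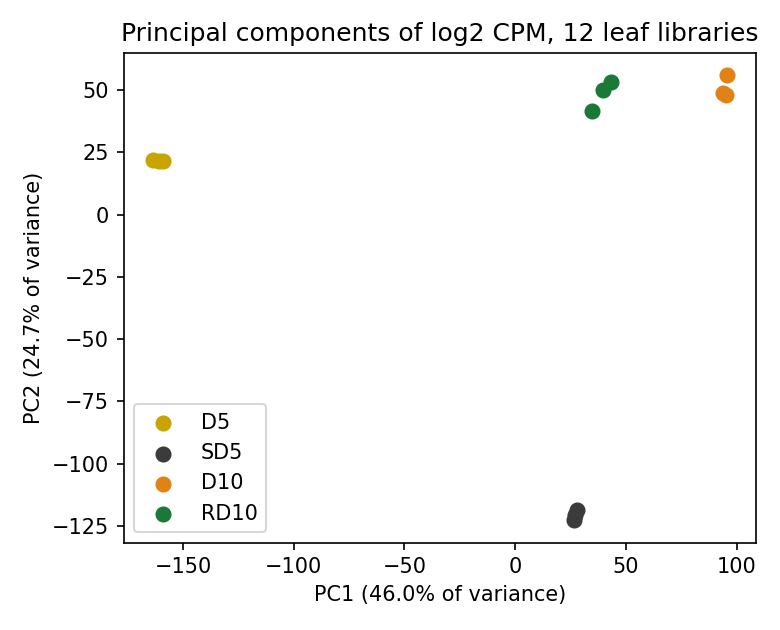
Each point is 1 library, placed by its first and second principal component of log2 CPM (axes in component units, with the share of variance). The 3 D5 libraries sit between -164 and -159 on the first component, and the 3 SD5 libraries sit between -123 and -119 on the second.

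What 5 days of shade did to the leaf transcriptome was addressed by SD5 against D5. Genes of light capture were lower in shade. All 21 tested genes of the light-harvesting antenna, the chlorophyll-binding proteins that collect light, fell, with a median log2 fold change of -1.67 (camera, Benjamini-Hochberg adjusted p = 6.9e-18). A gene outside that list described as chlorophyll A-B binding family, CSS024403 (scaffold 825, 411950 to 413775, plus strand), went from 2990.0 ± 166 CPM in D5 to 6.66 ± 0.391 in SD5, a log2 fold change of -8.81 ± 0.09 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.6e-16). That description alone does not settle whether its product collects light. A light-harvesting chlorophyll B-binding protein 3 gene, CSS047803, fell by 2.94 ± 0.06 on the log2 scale, from 2263 ± 157 to 295 ± 6.88 CPM. Of the 49 photosystem core and electron transport genes 44 fell and 0 rose (45 fell when adjusted over the list alone), with a median of -1.36 (camera adjusted p = 8.1e-21, and adjusted p = 0.051 with an estimated correlation). A gene for the gamma subunit of ATP synthase, CSS038007, went from 1488 ± 72.2 to 211 ± 11.4 CPM. It was at 345 ± 10.8 CPM in D10, picked on day 10, and SD5 stood at -0.71 against D10 on the log2 scale. Of these 49 genes 35 were higher in D5 than in each of the other 3 groups. Transcripts of plastid-genome type moved with these groups, with 36 of 40 tested genes lower and a median of -2.51.

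Chlorophyll synthesis was lower in shade as well, with 13 of 20 genes down and 5 up (median -1.05, camera adjusted p = 1.3e-06). The H subunit of magnesium chelatase, which puts magnesium into the chlorophyll ring (CSS007623, scaffold 2153, 860117 to 865854, minus strand), fell by 4.33 ± 0.10 on the log2 scale, from 1388 ± 172 to 69.0 ± 8.59 CPM. Glutamyl-tRNA reductase, the entry enzyme of the pathway (CSS040303), went from 621 ± 37.6 to 86.9 ± 1.94 CPM. A protochlorophyllide oxidoreductase A gene, CSS044068, went from 779 ± 33.5 to 143 ± 15.2 CPM. It was at 176 ± 8.55 CPM in unshaded D10, and SD5 stood at -0.30 against D10 on the log2 scale. In chlorophyll breakdown 5 of 10 genes fell and 4 rose (median -0.53, camera adjusted p = 0.025, and adjusted p = 0.19 with an estimated correlation): a pheophorbide a oxygenase family gene, CSS053198, fell by 3.40 ± 0.06 and a chlorophyllase 1 gene, CSS028913, rose by 1.71 ± 0.11. Against D10, CSS053198 stood at -0.57 and CSS028913 at 0.83. Carotenoid synthesis had 13 of 17 genes down and 2 up (median -1.14, camera adjusted p = 1.3e-07), among them zeaxanthin epoxidase, CSS042660, at 516 ± 18.3 CPM in D5 and 70.9 ± 3.74 in SD5. Of 7 carotenoid cleavage genes 4 rose and 2 fell, and the list did not pass (camera adjusted p = 0.83). Nine-cis-epoxycarotenoid dioxygenase 3, of abscisic acid synthesis (CSS033469), rose by 2.16 ± 0.08, while its relative number 4 (CSS034757) fell by 2.1 ± 0.06.

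The Calvin cycle list, the carbon-fixing reactions, had 26 of 36 genes lower and 4 higher (median -0.92, camera adjusted p = 1.1e-13). With members matched by the first names alone that median was -0.22, and the list still passed. A rubisco activase gene, CSS047135, fell by 7.03 ± 0.10, from 1053 ± 53.4 to 8.05 ± 1.10 CPM. Photoprotection and early light-induced genes had 24 of 27 lower and 0 higher (median -1.52, camera adjusted p = 1.3e-11), and 21 of them were higher in D5 than in each other group. Ascorbate peroxidase 1, CSS032148, fell by 2.31 ± 0.07 against D5, and stood 0.87 higher than in D10. All 11 plastid ribosome genes fell (median -1.38, camera adjusted p = 5.0e-06). Cytosolic ribosome genes had 75 of 92 lower and 3 higher (median -1.12, camera adjusted p = 1.3e-11, and adjusted p = 0.15 with an estimated correlation), and 67 of the 92 were higher in D5 than in each other group. Against D10 that list did not pass (median -0.099, camera adjusted p = 0.43). Starch and sugar genes went both ways, with 27 of 67 up and 27 down (29 up when adjusted over the list alone), and the list did not pass (median 0.10, while camera gave the direction as down, adjusted p = 0.83). Against D10 its median was -0.058. Among light signalling genes 9 of 30 rose and 13 fell (14 fell when adjusted over the list alone; camera adjusted p = 0.66). The clock list had 13 of 24 genes lower and 4 higher (5 higher when adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.0074, and adjusted p = 0.11 with an estimated correlation). With members matched by the first names alone, 119 genes of which 8 are in the list, the median was 0.35 and the call ended. Pseudo-response regulator 5, CSS050021, fell by 3.78 ± 0.07, from 535 ± 16.7 to 38.8 ± 3.04 CPM.

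The lists behind catechins, theanine and caffeine, the best known secondary metabolites of tea, held genes that rose and genes that fell in SD5 against D5. Of 13 phenylpropanoid entry genes 4 rose and 4 fell (5 rose when adjusted over the list alone), and the list did not pass (median 0.16, while camera gave the direction as down, adjusted p = 0.70). Against D10, which also differs in the day of picking, it did pass with the preset correlation (median -1.38, camera adjusted p = 2.3e-12). There 11 of 13 genes were lower in SD5 and 0 higher. Of these, 4 were lower than in both unshaded groups. Cinnamate 4-hydroxylase, CSS028430, fell by 1.48 ± 0.05, from 364 ± 8.41 to 130.4 ± 5.61 CPM, while 4-coumarate:CoA ligase 3, CSS005816, rose by 1.12 ± 0.06 against D5. It stood at -1.47 against D10. In flavonoid and catechin synthesis 8 of 28 genes rose and 13 fell (15 fell when adjusted over the list alone), and the list did not pass (median -0.55, camera adjusted p = 0.41). Against D10 this list passed too (median -0.98, camera adjusted p = 4.3e-13). There 18 of 28 genes were lower in SD5 and 1 was higher. Of these, 11 were lower than in both unshaded groups. The phenylpropanoid and flavonoid lists were both higher in D10 than in D5 (medians 1.65 and 1.17). Shade and time thus cannot be separated in their calls against D10. A chalcone and stilbene synthase family gene, CSS019164, fell by 1.65 ± 0.06, from 716 ± 26.0 to 227 ± 10.7 CPM, and a chalcone-flavanone isomerase family gene, CSS001609, rose by 1.72 ± 0.07 against D5 and stood at -0.66 against D10. The chalcone synthase family gene with the highest mean CPM over the libraries, CSS008567, rose by 0.23 ± 0.05 against D5. It stood at -1.15 against D10. Of the 24 theanine and ammonium assimilation genes 15 fell and 6 rose (median -0.82, camera adjusted p = 0.022, and adjusted p = 0.051 with an estimated correlation). The call ended with members matched by the first names alone (median -0.49). Glutamate synthase 1, CSS029241, fell by 2.21 ± 0.07 and glutamine synthetase 2, CSS030824, by 1.37 ± 0.05, while arginine decarboxylase 2, of polyamine synthesis (CSS045462), rose by 2.54 ± 0.06, from 292 ± 8.98 to 1697 ± 35.8 CPM. Purine supply genes for caffeine had 15 of 21 higher and 5 lower (median 0.58, camera adjusted p = 0.042, and adjusted p = 0.10 with an estimated correlation). An S-adenosylmethionine synthetase 1 gene, CSS014370, rose by 2.64 ± 0.05 against D5 and stood at 0.45 against D10. The call of this last list ended with the first names alone (median 0.35), without D5 replicate 2 (0.59) and without D5 replicate 3 (0.53). Against D10 its median was -0.11. The caffeine N-methyltransferases are not analysed here.

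**Figure D2:**
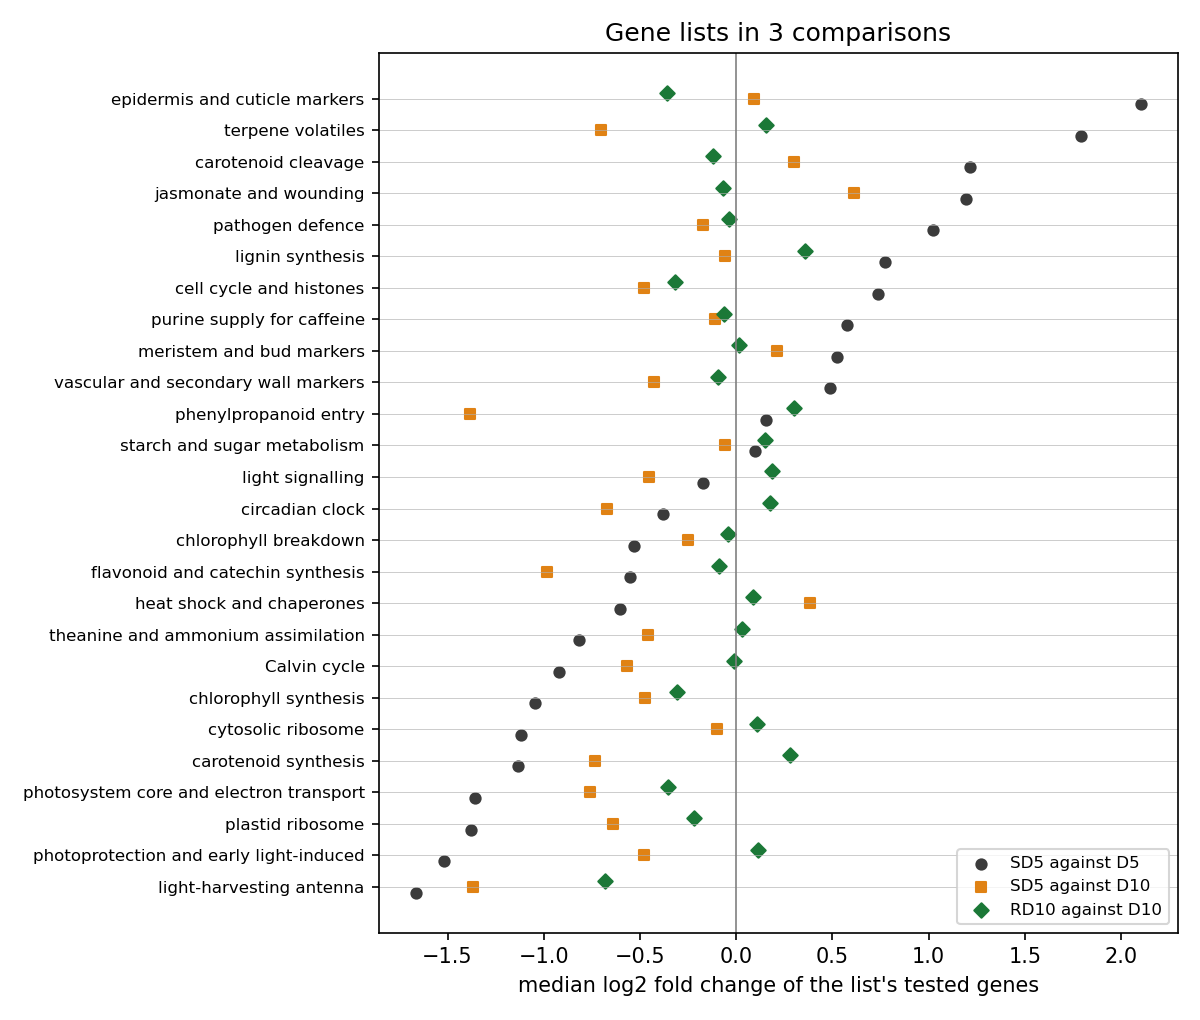
Each line is 1 gene list, and each point the median log2 fold change of its tested genes in SD5 against D5 (circles), SD5 against D10 (squares) or RD10 against D10 (diamonds). The antenna list lies at -1.67, -1.37 and -0.68, and the cuticle list at 2.1, 0.09 and -0.36.

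The jasmonate and wounding list had 22 of 34 genes higher and 5 lower (23 higher when adjusted over the list alone), with a median of 1.19 in SD5 against D5 (camera adjusted p = 1.5e-07). Jasmonate-zim-domain protein 1, a repressor of jasmonate responses that is itself induced by jasmonate (CSS010781), rose by 3.11 ± 0.05, from 159 ± 0.511 to 1371 ± 21.8 CPM. Epidermis and cuticle markers had 21 of 24 genes higher and 1 lower (median 2.1, camera adjusted p = 1.7e-13). Among them 3-ketoacyl-CoA synthase 6, of wax synthesis (CSS010938), had 0 counts in D5 and 11.5 ± 0.658 CPM in SD5, at least 742-fold higher from a floor of 3 counts over the group. It was lower in SD5 than in D10 (log2 fold change -1.99). Intervals and floors cover counting error only. Outside the list, a pectin lyase-like gene, CSS038825, was also at 0 in D5 and at least 11134-fold higher in SD5 (173 ± 9.48 CPM). This gene too was lower in SD5 than in D10 (-1.24). Pathogen defence had 46 of 85 higher and 11 lower (47 higher when adjusted over the list alone; median 1.02, camera adjusted p = 5.8e-04, and adjusted p = 0.063 with an estimated correlation). Terpene volatiles had 18 of 31 higher and 6 lower (median 1.79, camera adjusted p = 0.0012, and adjusted p = 0.051 with an estimated correlation). Lignin synthesis had 38 of 76 higher and 20 lower (39 higher when adjusted over the list alone; median 0.77, camera adjusted p = 0.039, and adjusted p = 0.051 with an estimated correlation). Cell cycle and histone genes had 49 of 97 higher and 15 lower (median 0.74, camera adjusted p = 0.018, and adjusted p = 0.10 with an estimated correlation). Vascular and secondary wall markers had 10 of 28 higher and 5 lower (median 0.49, camera adjusted p = 0.025, and adjusted p = 0.066 with an estimated correlation). Calls ended for cell cycle genes with the first names alone (median 0.79), for vascular markers without D5 replicate 3 (0.49) and for lignin with library totals as the only scaling (1.06). Of 45 meristem and bud markers 17 rose and 10 fell, and the list did not pass (camera adjusted p = 0.70).

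Heat shock and chaperone genes fell in SD5 against D5, with 94 of 169 lower and 24 higher (95 and 27 when adjusted over the list alone), and a median of -0.60 (camera adjusted p = 2.9e-16). A heat shock protein gene, CSS033163, went from 1521 ± 61.7 to 31.7 ± 1.04 CPM. These groups are also those in which the D5 libraries stood apart: 80 of the 169 heat shock genes were higher in D5 than in each of the other 3 groups, and 20 of the 24 cuticle, 44 of the 97 cell cycle, 18 of the 31 terpene, 35 of the 85 pathogen and 17 of the 34 jasmonate genes were lower in D5 than in each. Against D10 instead of D5, the SD5 median was 0.38 for heat shock, -0.48 for cell cycle, -0.70 for terpenes, -0.17 for pathogen defence, -0.06 for lignin and -0.43 for vascular markers, each with the other sign than against D5. The cuticle median was 0.09 against D10, with 8 genes higher and 8 lower, and camera gave the direction as down. Lists were tested against D10 with the preset correlation only. Of the lists just given, heat shock, cell cycle and terpenes passed against D10, and pathogen defence, lignin, vascular and cuticle did not. Against D10 the medians kept their sign for the antenna (-1.37, with all 21 genes lower than in both unshaded groups), photosystem (-0.76), chlorophyll synthesis (-0.47), carotenoid synthesis (-0.74), Calvin cycle (-0.57), photoprotection (-0.48), plastid ribosome (-0.64), theanine (-0.46), clock (-0.67) and jasmonate (0.61) lists. Photoprotection passed narrowly against D10, with 17 of 27 genes lower and 5 higher (camera adjusted p = 0.0489). Chlorophyll breakdown did not pass against D10 (-0.25, camera adjusted p = 0.085), and light signalling did (-0.45, camera adjusted p = 0.0082).

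**Figure D3:**
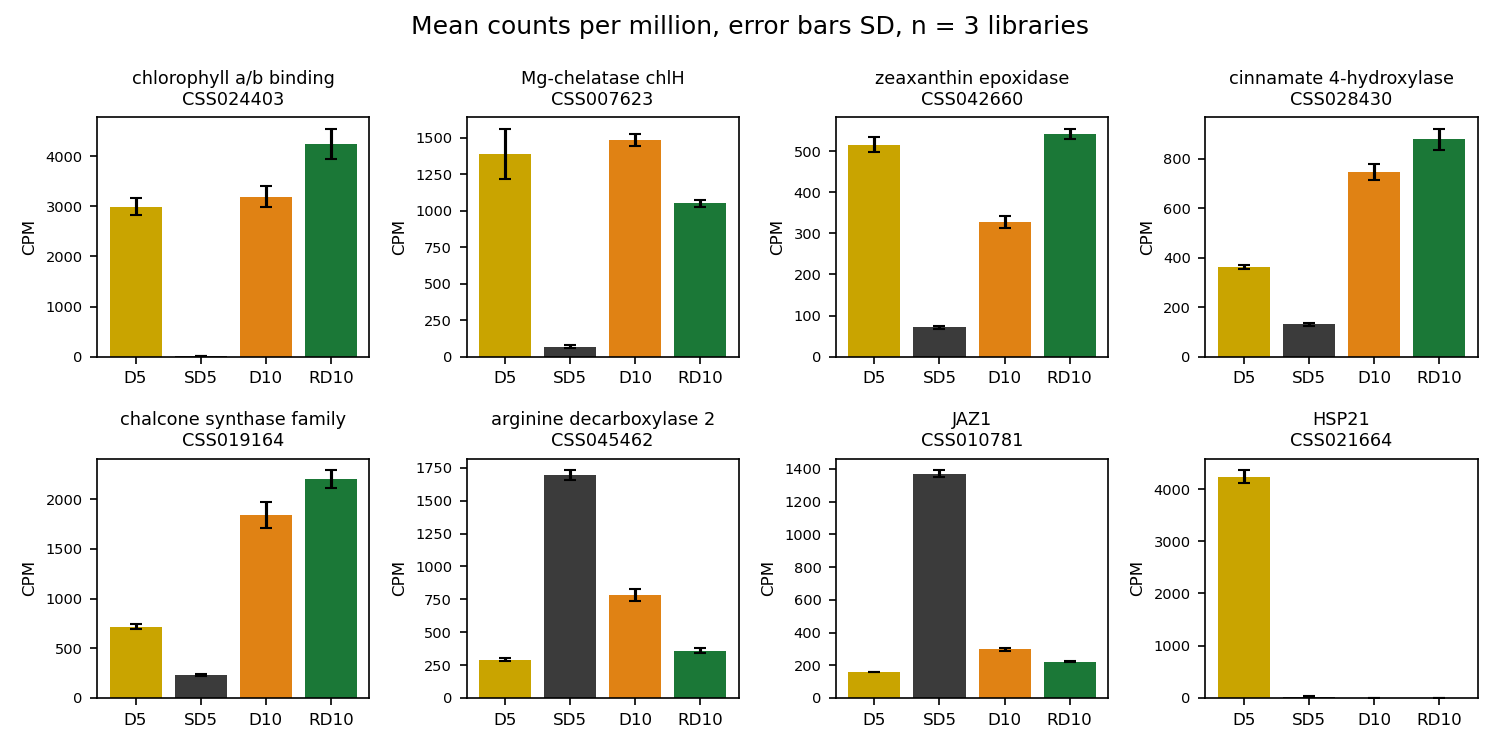
Bars are mean CPM of 3 libraries in each group and error bars are SD, on axes that start at 0. CSS024403 stands at 6.66 CPM in SD5 against 2990.0 in D5 and 3192 in D10, CSS010781 peaks in SD5 at 1371 and CSS021664 stands at 4234 in D5 and 26.8 or less in the other groups.

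In total 17212 of 26277 genes passed in SD5 against D5 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 9149 higher and 8063 lower, or 53.2% higher. With library totals in place of TMM the split was 11848 higher and 5737 lower, or 67.4% higher, and the median log2 fold change of all tested genes was 0.35, against 0.07 with TMM. The same change of scaling took that median to 0.13 from 0.00291 in D10 against D5 and to -0.29 from -0.07 in the difference of the contrasts. A change of at least 2-fold was reached by 5171 higher and 3644 lower genes. SD5 against D10 also differs in the day of picking, so it mixes shade with time. With D10 as the unshaded group 14807 genes passed, and 3701 were higher and 3466 lower in SD5 than in both unshaded groups. Those with the same direction against both made up 41.6% of the 17212 shade calls. Another 3869 genes, or 22.5% of the shade calls, were called in opposite directions against D5 and against D10. Of the 26 lists tested, 20 passed with the preset correlation and 9 with an estimated one: chlorophyll synthesis (adjusted p = 0.019 with an estimated correlation), antenna (0.035), carotenoid synthesis (0.016), photoprotection (0.028), heat shock (3.6e-04), plastid ribosome (0.039), Calvin cycle (0.019), jasmonate (0.013) and cuticle (0.016). Antenna, heat shock, thaumatin and oxidoreductase genes belong to multigene families whose near-identical copies may share reads, so values of single copies are uncertain.

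Whether leaves returned to the unshaded state after 5 days of light was addressed by RD10 against D10. Antenna genes were still lower, with 19 of 21 down and 0 up, by a smaller median of -0.68 (camera adjusted p = 8.9e-18, and adjusted p = 0.061 with an estimated correlation). With the first names alone, which matched 5 genes of that list, the median was -1.19. Chlorophyll A/B binding protein 1, CSS037525, was at 7115 ± 345 CPM in D10 and 2627 ± 206 in RD10, a log2 fold change of -1.44 ± 0.06 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.9e-09), whereas CSS024403, outside the list, rose by 0.41 ± 0.07 in relit leaves, to 4240.2 ± 304 CPM. Photosystem genes had 29 of 49 lower and 2 higher (31 and 4 when adjusted over the list alone; median -0.35, camera adjusted p = 4.4e-07, and adjusted p = 0.31 with an estimated correlation), among them photosystem II subunit O-2, CSS041754, at -1.14 ± 0.05. Chlorophyll synthesis had 12 of 20 lower and 0 higher (13 lower when adjusted over the list alone; median -0.31, camera adjusted p = 2.1e-07, and adjusted p = 0.061 with an estimated correlation), among them a protochlorophyllide oxidoreductase A gene, CSS013120, which fell by 2.40 ± 0.08.

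The carotenoid synthesis and phenylpropanoid entry lists were higher in relit leaves. Carotenoid synthesis had 9 of 17 genes higher and 1 lower (median 0.28, camera adjusted p = 0.011, and adjusted p = 0.12 with an estimated correlation), with zeaxanthin epoxidase, CSS042660, up by 0.72 ± 0.05. Phenylpropanoid entry had 6 of 13 higher and 0 lower (median 0.30, camera adjusted p = 5.8e-04, and adjusted p = 0.087 with an estimated correlation). Phenylalanine ammonia lyase 1, the first enzyme of that route (CSS002284), rose by 1.84 ± 0.07, from 27.4 ± 0.358 to 98.1 ± 8.0 CPM. In flavonoid and catechin synthesis 6 of 28 genes rose and 7 fell (median -0.09, while camera gave the direction as up, adjusted p = 0.94), with flavanone 3-hydroxylase, CSS020883, up by 0.50 ± 0.05. Theanine and ammonium assimilation had 6 of 24 higher and 6 lower (median 0.03, while camera gave the direction as down, adjusted p = 0.94): nitrite reductase 1, CSS001978, rose by 1.61 ± 0.08 and arginine decarboxylase 2, CSS045462, fell by 1.12 ± 0.06. Purine supply genes had 4 of 21 higher and 3 lower (camera adjusted p = 0.90). The starch and sugar list passed (25 of 67 higher, 14 lower, or 27 and 17 when adjusted over the list alone; median 0.15, camera adjusted p = 0.0024, and adjusted p = 0.25 with an estimated correlation), and alpha-amylase-like 2, CSS010451, rose by 1.81 ± 0.10. The call of the starch and sugar list ended with the first names alone (median 0.0093).

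Cuticle markers in RD10 against D10 had 12 of 24 lower and 0 higher (median -0.36, camera adjusted p = 2.3e-08, and adjusted p = 0.061 with an estimated correlation), and 3-ketoacyl-CoA synthase 6, CSS010938, fell by 2.19 ± 0.10. Cell cycle and histone genes had 30 of 97 lower and 4 higher (32 lower when adjusted over the list alone; median -0.32, camera adjusted p = 0.0016, and adjusted p = 0.087 with an estimated correlation). The call of the cell cycle list ended with the first names alone (-0.34). Meristem and bud markers had 6 of 45 higher and 7 lower, and the list did not pass (camera adjusted p = 0.94). Heat shock genes had 45 of 169 higher and 22 lower (47 and 23 when adjusted over the list alone; median 0.09, camera adjusted p = 0.022, and adjusted p = 0.087 with an estimated correlation). Of 40 genes of plastid-genome type 39 were lower (median -4.20), and all 14 tested genes of mitochondrial-genome type were lower too (median -3.60). Photosystem II reaction center protein B, CSS049947, went from 187 ± 32.9 CPM in D10 to 2.09 ± 1.35 in RD10. In all, 8777 genes passed, 4453 higher and 4324 lower, and 882 and 1402 of them by at least 2-fold (edgeR quasi-likelihood test). The commoner direction depended on the scaling: 5632 were higher and 3681 lower, or 60.5% higher, with library totals, and 4034 and 4593, or 46.8% higher, with DESeq2 size factors. Of the 26 lists 9 passed with the preset correlation and 0 with an estimated one.

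Whether the contrast of shaded leaves on day 5 differed from that of relit leaves on day 10 was tested by the difference of the 2 contrasts. In it 16277 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 7805 higher and 8472 lower on day 10. No group still under the net was picked on day 10, so day and relighting cannot be separated in this difference. With library totals 6257 were higher and 10046 lower, or 38.4% higher. Antenna genes were higher in this difference for 15 of 21 genes and lower for 2 (median 1.19, camera adjusted p = 2.2e-05, and adjusted p = 0.20 with an estimated correlation), photosystem genes for 39 and 2 of 49 (median 0.91, camera adjusted p = 4.3e-09, and adjusted p = 0.18 with an estimated correlation) and carotenoid synthesis genes for 13 and 1 of 17 (14 higher when adjusted over the list alone; median 1.36, camera adjusted p = 2.4e-07). With the first names alone the antenna median turned to -0.11 and its call ended, and the photosystem median was 0.58. Jasmonate genes were lower in it for 21 of 34 and higher for 4 (22 lower when adjusted over the list alone; median -1.15, camera adjusted p = 1.3e-06), and cuticle genes lower for 21 of 24 (median -2.63, camera adjusted p = 2.1e-15). With an estimated correlation carotenoid synthesis, jasmonate, cuticle and heat shock, 4 of the 15 lists, still passed. Pinoresinol reductase 1, of lignan synthesis (CSS036528), fell by 7.70 ± 0.39 in SD5 against D5 and rose by 4.98 ± 0.36 in RD10 against D10. It stood at 28.2 ± 0.71 CPM in D5, 0.126 ± 0.13 in SD5, 0.347 ± 0.113 in D10 and 11.2 ± 1.37 in RD10. Unshaded D10 leaves were thus low in it as well, and SD5 stood at -1.40 against D10. Of the 9149 genes higher in shade, 1027 were still higher in RD10 than in D10, 5571 did not pass and 2551 were lower; of the 8063 lower in shade, 775 were still lower, 4889 did not pass and 2399 were higher. The slope of the relit on the shade fold changes was -0.119 across the 17212 shade genes, with r = -0.259 and 35.2% of signs alike. Genes are not independent replicates, so no p is given, and the D5 libraries, which stood apart, enter the shade contrast.

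Relit against shaded leaves, RD10 against SD5, also differs in the day of picking. Antenna genes were higher for 14 of 21 and lower for 2 (median 0.73, camera adjusted p = 7.0e-05, and adjusted p = 0.28 with an estimated correlation), and CSS024403, outside the list, rose by 9.32 ± 0.10 on the log2 scale (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.6e-16). With the first names alone the antenna median was 0.13 and its call ended. Phenylpropanoid entry genes were higher for 11 of 13 and lower for 0 (median 1.71, camera adjusted p = 2.9e-16), flavonoid and catechin genes for 17 and 2 of 28 (median 0.79, camera adjusted p = 2.3e-11), carotenoid synthesis genes for 15 and 1 of 17 (median 0.90, camera adjusted p = 5.3e-07), Calvin cycle genes for 22 and 5 of 36 (24 higher when adjusted over the list alone; median 0.79, camera adjusted p = 9.6e-10) and light signalling genes for 19 and 4 of 30 (median 0.49, camera adjusted p = 5.6e-04). The Calvin cycle median was 0.29 with the first names alone, and the list still passed. Jasmonate genes were lower for 19 of 34 and higher for 7 (median -0.50, camera adjusted p = 1.7e-06). A Kunitz family protease inhibitor gene, CSS026445, fell from 98.5 ± 1.09 to 1.66 ± 0.136 CPM, and an auxin-responsive GH3 family gene, CSS032334, from 147 ± 8.64 to 3.93 ± 1.17. Plastid-genome type transcripts moved with the antenna, 37 of 40 higher (median 3.28). In all 14758 genes passed, 7281 higher and 7477 lower, and with DESeq2 size factors 7588 were higher and 7180 lower. Of the lists 17 passed, of which 6 passed with an estimated correlation.

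Unshaded leaves of the 2 days, D10 against D5, give the background of time. Heat shock genes were lower in D10 for 114 of 169 and higher for 18 (115 lower when adjusted over the list alone; median -0.92, camera adjusted p = 8.8e-26), and heat shock protein 21, a plastid chaperone (CSS021664, scaffold 157, 623990 to 625496, minus strand), stood at 4234 ± 128 CPM in D5 and 3.18 ± 0.71 in D10, a log2 fold change of -10.38 ± 0.14 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.5e-15). Cuticle markers were higher for 21 of 24 and lower for 0 (22 higher when adjusted over the list alone; median 2.1, camera adjusted p = 6.0e-15), and the pectin lyase-like gene CSS038825, outside the list, was at least 26251-fold higher, from 0 counts in D5. Cell cycle and histone genes were higher for 67 of 97 and lower for 10 (11 lower when adjusted over the list alone; median 1.28, camera adjusted p = 1.9e-06), terpene genes for 23 and 4 of 31 (24 higher when adjusted over the list alone; median 1.89, camera adjusted p = 4.1e-07), phenylpropanoid entry genes for 10 and 1 of 13 (median 1.65, camera adjusted p = 1.9e-06) and flavonoid and catechin genes for 19 and 4 of 28 (median 1.17, camera adjusted p = 4.1e-06). Cytosolic ribosome genes were lower for 74 of 92 and higher for 2 (75 lower when adjusted over the list alone; median -0.93, camera adjusted p = 2.0e-09, and adjusted p = 0.23 with an estimated correlation). Plastid-genome type genes were higher in D10 for 39 of 40 (median 4.69) and photosystem genes of the nucleus lower for 39 of 49 and higher for 1 (median -0.66, camera adjusted p = 5.8e-07, and adjusted p = 0.24 with an estimated correlation). The call of the photosystem list ended with the first names alone (median -0.14). In all 18206 genes passed, 9169 higher and 9037 lower, and 19 lists, of which 9 passed with an estimated correlation.

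Because both contrasts use the D5 libraries, the fold changes of SD5 against D5 and of D10 against D5 share chance values. Across 26277 genes r was 0.706, against 0.501 in simulated unchanged groups, and the covariance was 2.26 against 0.0971. The simulated r comes from chance values alone, so it is no baseline for the r of real effects. Both contrasts had 6493 genes higher and 5883 lower, where independent lists of these sizes would share 3192 and 2773. Simulated groups shared 0 and 0, which was all but fixed because they held no effect to call. SD5 against D5 and SD5 against D10 share the SD5 libraries: r was 0.257 against 0.473 simulated, and the covariance was 0.603 against 0.09. In both, 3701 genes were higher and 3466 lower, where independent lists would share 2650 and 2208 and simulated groups, again without effects, 0 and 0. Another 3869 genes were called in opposite directions. The 3 shared libraries cannot be split with at least 2 in each part, so some of the excess may come from sharing them. The simulation held only the spread between replicates, and by its covariances that spread was a small part of the observed covariance in both pairs. A shift common to the 3 libraries of the shared group would enter both contrasts and was not simulated. The simulation therefore cannot show how much of the covariance comes from sharing a group.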

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

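The tests of the difference, the D10 against D5 contrast with its lists and the splits of the libraries were planned before the data were examined. The use of list values to weigh explanations, and the tests of library labels, heat shock members, organelle-genome type genes, library totals, first names, D10 as the unshaded group and clock genes, were chosen after the results were seen. The contrast of treated with unshaded leaves differed between day 5 (shaded) and day 10 (relit) for 16277 genes by edgeR's test of the difference itself. Day and relighting change together in that difference, so it does not show that the response to shade depends on the day. The same test of the difference, with camera, passed for 15 of 26 gene lists, and for 4 with an estimated correlation. Of the genes called on both days, 4950 went opposite ways and 1802 went the same way. Calls of opposite sign all but fix the outcome of the test of the difference, so that test adds nothing for those genes. In the difference, 1 of 100 drawn splits of the 12 libraries gave as many genes, the real one itself, and the highest of the others gave 3539. The groups lay far apart, so most drawn splits mix unlike libraries and raise the spread. Those splits thus show that the groups differ, and they cannot decide whether the 2 contrasts do. For the 3-against-3 contrasts 10 splits are too few for a share under 0.05: the real counts were 17212 for SD5 against D5, 8777 for RD10 against D10, 14758 for RD10 against SD5 and 18206 for D10 against D5, each reached by 1 split, the real one, with highest others of 0, 1, 2 and 1.

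The D5 libraries stood apart from all other groups, and D5 enters both the shade contrast and its difference. A wrong label on a single D5 library is argued against, since 0 of the 3 had its highest correlation with a library of another group. That restates the closeness of replicates given above, and it could not show an exchange of whole groups. Older leaves in D5 should lower both cell cycle and cytosolic ribosome genes there. Cell cycle genes were lower in D5 (median 1.28 in D10 against D5), but ribosome genes were higher in D5 (median -0.93). That ribosome call ended when camera used an estimated correlation (adjusted p = 0.23). The ribosome genes thus argue only weakly against leaf age as the whole cause, and leaf age as part of it stays open. Warmer leaves at the D5 picking may account for part of the pattern, since 80 heat shock list members were higher in D5 than in each other group and 11 were lower, but the labels give no temperature and cuticle and cell cycle genes are left open. A difference in the hour or weather of picking cannot be separated from the group with these labels.

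Organelle-genome type transcripts were far higher in D10 than in the other groups. Plastid transcription that follows the nuclear photosystem genes is argued against for D10 against D5. There 39 of 49 of those genes were lower in D10 and 1 was higher (median -0.66) while plastid-genome type genes were higher (median 4.69). The photosystem call ended when camera used an estimated correlation (adjusted p = 0.24). Both medians had the same sign in SD5 against D5 (-1.36 and -2.51), RD10 against D10 (-0.35 and -4.20) and RD10 against SD5 (0.36 and 3.28). In the difference their signs were opposite (0.91 and -1.36). With list members by the first names alone the photosystem median was -0.14 and the list no longer passed. Of the 45 genes matched by the first names, 25 are in the list. Whether the others are nuclear was not checked, so that median bears little on the nuclear genes. RNA without poly(A) tails carried into the D10 libraries to a greater degree is a candidate explanation, since mitochondrial-genome type genes moved the same way, with a median of -3.60 in RD10 against D10 and 100% of 14 members lower. A biological change in both organelles at once would look alike and stays open.

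Antenna and photosystem genes were lower in shade. Scaling is argued against as the whole cause, since with library totals alone the antenna median was -1.38 with 0 members higher, and so are the D5 libraries alone, since against D10 the antenna median was -1.37 and the photosystem median -0.76. SD5 against D10 also differs in the day of picking, so those medians are not free of time. Another hour of picking for the shaded leaves cannot be told apart from shade here: 76.5% of called clock genes went the commoner way against D5 and 59.1% against D10, and the labels give no hours. A response to shade, the treatment the design names, may account for the pattern, as a hypothesis found and tested on the same libraries.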

How the results depend on the processing

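Library totals, organelle-free fits, first names alone and D10 as the unshaded group were chosen after the results were seen; all other alternatives were set before the data were examined. Counts of genes per contrast stayed within 1.5 times under DESeq2 size factors, DESeq2's Wald test, no low-count filter, library totals, fits to the compared groups, organelle-free fits and leaving out each library. They ranged over left-out libraries from 16188 to 16604 for SD5 against D5, 7036 to 7685 for RD10 against D10, 15498 to 16028 for the difference, 13440 to 13768 for RD10 against SD5 and 17206 to 17641 for D10 against D5. Of the RD10 against D10 genes 34.3% were lost in at least 1 of these fits, the largest such share of the 5 contrasts. Named genes kept their direction under DESeq2 size factors, DESeq2's Wald test, library totals, the replicate block and each left-out library, and 1 lost its call, CSS024626 under DESeq2's Wald test in RD10 against D10. With D10 as the unshaded group, genes given above for SD5 against D5 that took the other sign were CSS038825 (-1.24), CSS010938 (-1.99), CSS005816 (-1.47), CSS001609 (-0.66), CSS008567 (-1.15) and CSS032148 (0.87).

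A minimum change of 2-fold left 8815 genes in SD5 against D5, 2284 in RD10 against D10, 10123 in the difference, 6060 in RD10 against SD5 and 9550 in D10 against D5, fewer by the construction of that threshold. The recovery slope was -0.108 with no low-count filter, -0.106 with library totals, -0.130 without organelle-genome type genes and -0.122 to -0.104 over left-out libraries, the lowest without RD10 replicate 3 and the highest without D5 replicate 1; the cause was not tested. With the replicate number as a block, 16920 genes passed in SD5 against D5, 8184 in RD10 against D10, 15924 in the difference, 14311 in RD10 against SD5 and 17877 in D10 against D5, and deviations of libraries with the same number correlated between -0.0362 and 0.0423 over 12 pairs, so the numbers do not pair the libraries.

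With an estimated inter-gene correlation the lists past 0.05 fell to 9 for SD5 against D5, 0 for RD10 against D10, 4 for the difference, 6 for RD10 against SD5 and 9 for D10 against D5. Fry, which asks whether a list moves one way without comparing it with other genes, gave 18 for RD10 against D10 and 26 for the difference. With first names only, 22 of the 26 lists had enough members to test; 9 of them passed in the difference and 9 in RD10 against SD5, and medians turned for the clock list (0.35 in SD5 against D5, -0.44 in the difference, 0.53 in D10 against D5), which shared 8 members, for the antenna list (0.29 in D10 against D5 and -0.11 in the difference), of which they matched 5 of 22, and for the Calvin cycle list (0.090 in D10 against D5), lists that passed in neither setting left aside. They ended 18 calls: theanine (-0.49), purine (0.35) and cell cycle (0.79) in SD5 against D5, starch (0.0093) and cell cycle (-0.34) in RD10 against D10, chlorophyll synthesis (1.40), antenna, Calvin cycle (0.20) and terpenes (-1.07) in the difference, antenna (0.13), theanine (0.31), photoprotection (0.31), starch (0.011), lignin (0.31) and cuticle (-0.48) in RD10 against SD5, and photosystem (-0.14), purine (0.39) and Calvin cycle in D10 against D5. Calls gained in the same direction were 3, vascular markers in the difference (-0.79) and light signalling (0.66) and starch (0.59) in D10 against D5. The clock list (0.53) also gained a call in D10 against D5, with its direction turned. Leaving out a library ended 11 list calls: purine without D5 replicate 2 or 3 and vascular without D5 replicate 3 in SD5 against D5, plastid ribosome without SD5 replicate 2 or RD10 replicate 3 in RD10 against SD5, and, in D10 against D5, antenna without D5 replicate 1, D10 replicate 2 or D10 replicate 3, plastid ribosome without D5 replicate 1 or D10 replicate 2, and jasmonate without D5 replicate 2. It gained 3, all without RD10 replicate 3: light signalling (0.20) and plastid ribosome (-0.29) in RD10 against D10 and theanine in the difference (0.82), which the replicate block gained too (0.87). Antenna and plastid ribosome calls in D10 against D5 also ended with DESeq2 size factors and with library totals, which ended lignin in SD5 against D5 too. With D10 as the unshaded group, medians turned for the purine (-0.11), heat shock (0.38), lignin (-0.060), terpene (-0.70), pathogen (-0.17), cell cycle (-0.48) and vascular (-0.43) lists, and for the phenylpropanoid (-1.38) and starch (-0.058) lists, whose camera direction was down in both, and the test's direction turned for the cuticle list (median 0.092). SD5 against D10 also differs in the day of picking, and its lists were tested with the preset correlation only. There the phenylpropanoid, flavonoid (-0.98) and light signalling (-0.45) lists gained a call, and the cytosolic ribosome (-0.099) and chlorophyll breakdown (-0.25) lists lost theirs. The cause was not tested. In simulated SD5 against D5 counts 36.4% of genes changed 1.5-fold were recovered. Of genes changed 4-fold in shade 80.3% were recovered there, 60.6% in RD10 against D10 and 33.3% in the difference, where the simulated changes were smaller. The cutoff was stricter in the simulated than in the real SD5 against D5, so these shares do not carry over to the real contrasts. A gene that did not pass is still not shown to be unchanged.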

Other observations

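All tests in this part were chosen after the results were seen: 370 families of at least 8 genes sharing a description were tested with camera in each contrast, adjusted over the families. Of 61 GDSL-like lipase genes, a family with roles in cutin and wax, 40 rose and 6 fell in SD5 against D5 (median 1.55, camera adjusted p = 3.1e-10, and adjusted p = 0.21 with an estimated correlation), and in RD10 against D10 they were lower for 23 and higher for 5 (median -0.38, camera adjusted p = 2.6e-07, and adjusted p = 0.034 with an estimated correlation). They were also higher in unshaded D10 than in D5, 38 of 61 and 12 lower (median 1.93, camera adjusted p = 1.3e-11, and adjusted p = 0.054 with an estimated correlation). All 8 expansin A8 genes, which loosen cell walls, rose (median 3.56, camera adjusted p = 2.4e-05, and adjusted p = 0.22 with an estimated correlation), but against D10 6 were lower in shade and 0 higher (median -2.00, camera adjusted p = 2.2e-04, and adjusted p = 0.36 with an estimated correlation). TCP-1/cpn60 chaperonins, which fold proteins, were lower for 16 of 17 genes and higher for 0 in SD5 against D5 (median -1.01, camera adjusted p = 3.8e-05, and adjusted p = 0.27 with an estimated correlation). They were also lower in unshaded D10 than in D5, 15 of 17 and 1 higher (median -0.80, camera adjusted p = 3.1e-04, and adjusted p = 0.24 with an estimated correlation). No family passed in SD5 against D5 with an estimated correlation (0 of 51).

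Of 11 phosphate-responsive 1 family genes 10 rose against D5 (median 2.06, camera adjusted p = 1.9e-05, and adjusted p = 0.25 with an estimated correlation) and 10 rose against D10 (median 1.84, camera adjusted p = 2.7e-11, and adjusted p = 0.18 with an estimated correlation). All 11 were lower in RD10 than in SD5 (median -2.89, camera adjusted p = 3.9e-18, and adjusted p = 0.024 with an estimated correlation). All 8 genes described as ethylene responsive element binding factor 5 were lower in RD10 than in SD5 (median -3.20, camera adjusted p = 3.6e-08, and adjusted p = 0.059 with an estimated correlation). Genes described as senescence-related gene 1 were higher in RD10 than in D10 for 5 of 8 and lower for 0 (median 0.48, camera adjusted p = 2.4e-10, and adjusted p = 0.030 with an estimated correlation). Of 126 transposase-related hAT dimerisation genes, 68 were lower in RD10 than in D10 and 0 higher (median -1.87, camera adjusted p = 2.6e-11, and adjusted p = 0.37 with an estimated correlation). In the same contrast 39 of 40 plastid-genome type genes were lower (median -4.20). Between the unshaded groups, 181 of 242 pentatricopeptide repeat genes, which process organelle RNA, were lower in D10 and 3 higher (median -1.13, camera adjusted p = 6.2e-08, and adjusted p = 0.25 with an estimated correlation).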
